A study of Homo sapiens with 30 samples.

How the data were processed

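RNA was measured by sequencing in H295R, an established human adrenocortical carcinoma cell line that makes steroid hormones and is used as a model of the adrenal cortex. Cells had received 10 uM forskolin, a plant diterpene that activates adenylyl cyclase and so raises cyclic AMP, or the solvent DMSO alone for 48 h. There were 4 libraries in each group, made from poly(A)-selected RNA, and the labels place all 8 in batch 1. The series holds 30 samples. The other 22, from STARR-seq (a reporter assay of enhancer activity), capture STARR-seq around DENND1A and ATAC-seq (a measure of open chromatin), were not analysed here. Samples were grouped by their treatment label, and replicate numbers were taken from the same titles. The file names of the libraries titled replicate 4 carry another number, and the title was used.

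The authors used STAR, RSEM and DESeq2 with the human build hg38, per the submitters' processing notes. The versions and the annotation release are not given in the sources used here, and neither is the strandedness of the counting. Each library came as 1 RSEM gene table of 60483 versioned Ensembl genes. The deposited expected counts are RSEM's estimated fragments per gene, in which fragments that map to several genes are divided among them. The deposited TPM values are the same estimates divided by effective transcript length and scaled to a fixed total in each library, which keeps no depth. The deposited FPKM values divide by effective length and by the number of fragments, and they entered no test. The authors' tables also give each gene's length and effective length in bases, per the file headers, as means over the gene's transcripts weighted by their estimated abundance. Division of shared fragments makes the values of near-identical genes uncertain, here CYP11B1 and CYP11B2, HSD3B2 and HSD3B1, CYP21A2 and its pseudogene, AKR1C3 and its relatives, and mitochondrial genes and their nuclear copies. Overlapping and antisense genes could not be told apart where the counting ignored strand.

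Expected counts were rounded to whole numbers. Library totals lay between 23.5 and 29.4 x 1e6. A gene ID was paired with a symbol for 56321 of the 60483 IDs (93.1%), and where several IDs shared a symbol, the one with the highest total kept it, which left 1145 IDs under their Ensembl name. Gene coordinates came from the RefSeq annotation of GRCh38.p14, the same build as hg38. Genes were kept by edgeR's filterByExpr by group (15790 genes), scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, robust, R 4.3.3), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Positive log2 fold changes are higher in forskolin. CPM values are scaled by TMM. No source says that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

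Gene lists (31 lists, 606 entries) were written before the data were examined, together with the tests, the alternatives and the rule for named genes. Of the list members, 1 (SOD2) could not be matched by ID. Lists with at least 3 tested members (30 lists) were tested with limma 3.58.1 camera, which compares a list's genes with the other genes tested, at a preset inter-gene correlation of 0.01. Alternatives were a correlation estimated per list and fry, which tests the list's genes on their own. Members past the threshold are counted with p-values adjusted over all genes and adjusted over the list alone. Library composition was compared by exact two-sided permutation over the 70 assignments of 8 libraries, for which the smallest p is 0.0286. The isoform mix was read from RSEM's weighted transcript length, on the log2 scale, with limma (trend, robust) in the 10421 genes with a mean count of at least 100 and a length that varies. A first version let the variance follow the mean count instead; it was replaced by the planned trend on mean log2 length and is kept as an alternative, which also called 0 genes.

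The genes named are DENND1A, every tested member of the steroid synthesis list, the 10 genes with the highest and the 10 with the lowest log2 fold change and, of each other list described, up to 4 members with the lowest adjusted p. The highest and lowest were taken among genes with an adjusted p under 0.05, a mean count of at least 100, no overlap between the groups and a symbol that is not a clone, LOC, LINC, antisense or pseudogene name. For transcript length, the rule takes DENND1A and up to 5 genes past the threshold with the largest shift. NR5A1, MRAP, DKK1, DKK4, LUM, DCN, MALAT1, GSTO2, GAS5 and ABHD14A fall outside the rule and were chosen after their values were seen.

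The alternatives were DESeq2's size factors in edgeR, library size with no composition scaling, no filter on low counts, a filter of at least 1 CPM in at least 4 libraries, the DESeq2 1.42.0 Wald test, limma voom, glmTreat against a fold of 1.5, RSEM's effective length as an offset, limma on log2(TPM + 1), mitochondrially encoded genes left out, the replicate number as a term, and each library left out in turn. Leaving out forskolin replicates 3 and 4 together and removing each library's trend on transcript length (lowess, span 0.3) were added after seeing the data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Steps were tested on simulated data. With 200 genes changed among 15613 tested, drawn from the means and library sizes of forskolin against DMSO, the edgeR test recovered 43 of 67 genes changed 1.5-fold, 57 of 67 changed 2-fold and 66 of 66 changed 4-fold, and 9 of its 175 calls (5.14%) were false. The camera step found 10 of 10 lists of 20 genes shifted by 0.5 on the log2 scale, with 1 false call among 10 unshifted lists. The transcript length test over 10421 genes recovered 15 of 67 shifts of 0.1, 32 of 67 of 0.2 and 51 of 66 of 0.5 on the log2 scale, with 5 false calls. Simulated genes varied independently, while members of real lists can move together (estimated correlation 0.997 for the mitochondrial mRNAs). The simulation of counts also changed far fewer genes than the 6990 called in the data. It gave both groups the same spread per gene, and the edgeR test also fits a common spread. The real forskolin libraries differed more among themselves than the DMSO libraries. Chi-square per degree of freedom on counts was 16.1 to 212 between forskolin libraries and 2.95 to 10.9 between DMSO libraries. These rates may therefore not hold for the real data.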

Results

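Poly(A) RNA was sequenced from H295R adrenocortical cells after 48 h with 10 uM forskolin, which activates adenylyl cyclase, or with DMSO, in 4 libraries per group. Totals lay between 23.5 and 29.4 x 1e6 expected counts per library, and between 15448 and 16081 genes had at least 10 counts. The first principal component of log2 CPM held 59.8% of the variance and the next 13.8%. On the first, DMSO libraries lay from -42.5 to -33.1 and forskolin replicates 1 to 4 at 20.9, 31.9, 55.8 and 39.8. The forskolin libraries had the same order there as in their share of mitochondrial mRNAs, given below. On the next component they lay at 26.1, 28.0, -33.3 and -3.98. The comparison asks which genes cyclic AMP signalling changes in a steroid-producing cell, and the series title ties the work to DENND1A and testosterone production.

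Forskolin changed much of the measured transcriptome. Of 15790 genes tested, 3560 were higher and 3430 lower in forskolin (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, n = 4 per group). Of these, 716 of the higher and 567 of the lower genes changed at least 2-fold. Leaving out 1 library at a time, these were 542 (without forskolin replicate 3) to 931 and 536 to 598. They were 482 and 621 without forskolin replicates 3 and 4. With each library's trend on transcript length removed, they were 540 and 572, and 5574 of the 6990 calls kept their direction and call. The groups did not overlap in 6668 genes (42.2%), against 2.86% by chance. The balance of higher and lower calls depended on the scaling. TMM put 50.9% of the calls on the higher side. With library size alone, which moved the median of all genes by -0.24 on the log2 scale, 24.0% were higher (1674 higher and 5300 lower). On log2(TPM + 1), where the median moved by -0.49, 4.55% were higher (403 higher and 8450 lower). Fold changes below are relative to the TMM scaling. Against a fold of 1.5 (glmTreat), 484 genes were higher and 568 lower.

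Genes that make steroids from cholesterol mostly rose. Of 21 tested members of the steroid synthesis list, 13 rose and 4 fell (the same numbers adjusted over the list alone), with a median log2 fold change of 0.67 (camera, adjusted p = 2.3e-10; adjusted p = 0.022 with an estimated correlation). CYP17A1, whose product makes the precursors of androgens, went from 50.7 ± 1.58 to 222 ± 16.3 CPM (mean ± SD, n = 4), a log2 fold change of 2.13 ± 0.07 (SE; edgeR adjusted p = 1.2e-08). It lies on chromosome 10 at 102830531 to 102837413 (ENSG00000148795.5). HSD3B2, which makes progesterone-type from pregnenolone-type steroids, rose from 28.1 ± 1.45 to 130.2 ± 10.2 CPM (log2 fold change 2.21 ± 0.08). STAR, which moves cholesterol into mitochondria, rose 3.13-fold, from 203 ± 2.70 to 637 ± 86.1 CPM. CYP11A1, the side-chain cleavage enzyme, rose 1.59-fold, CYP21A2, the 21-hydroxylase, 3.35-fold and CYP19A1, the aromatase, 2.34-fold. The electron carriers FDX1, FDXR and POR rose by 1.97, 0.55 and 0.44 on the log2 scale. PAPSS2, which makes the sulphate donor for steroid sulphation, rose by 1.32, and CYB5A, a cofactor of the lyase reaction of CYP17A1, by 0.78. With library size alone, 11 of the list's genes rose and 5 fell with a median of 0.44, and the calls of FDXR (0.31, edgeR adjusted p = 0.061) and POR (0.21, edgeR adjusted p = 0.25) ended. On log2(TPM + 1), 8 of the list's genes were higher and 7 lower with a median of -0.03, and CYP11A1, FDXR and POR had values of -0.03, -0.05 and -0.27.

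The last steps of aldosterone and cortisol synthesis started from almost no signal. CYP11B2, the aldosterone synthase, had 9 counts over the 4 DMSO libraries and 200 over the 4 forskolin libraries, a ratio of 25.9 (95% exact interval 13.4 to 57.5). CYP11B1, the 11-hydroxylase of cortisol synthesis, had 10 and 117 counts (ratio 13.7, interval 7.17 to 29.2). The intervals cover counting error only, and the pair shares reads. In the opposite direction, SULT2A1, which sulphates DHEA, fell by 1.21 (SE 0.08) on the log2 scale, from 74.7 ± 5.57 to 32.3 ± 2.78 CPM. HSD11B2, which inactivates cortisol, fell by 1.56 from a low level (66 counts in DMSO and 19 in forskolin). STS, the steroid sulphatase, fell by 0.35, and AKR1C3, which reduces androstenedione to testosterone, fell by 0.37. The call of AKR1C3 ended in 5 of the 8 fits that left out 1 library, with edgeR adjusted p of 0.065 (without DMSO replicate 1), 0.093 (DMSO 3), 0.094 (DMSO 4), 0.057 (forskolin 1) and 0.092 (forskolin 2), and with the effective length offset (0.059). That of CYB5A ended without DMSO replicate 2 and without forskolin replicate 4 (edgeR adjusted p = 0.052 in each) and with no filter (0.078), and that of STS once each library's trend on transcript length was removed (log2 fold change -0.12, edgeR adjusted p = 0.21). HSD17B1, HSD17B3, HSD17B4 and SRD5A1 did not pass the test (log2 fold changes -0.03, 0.07, -0.24 and -0.12).

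**Figure D1:**
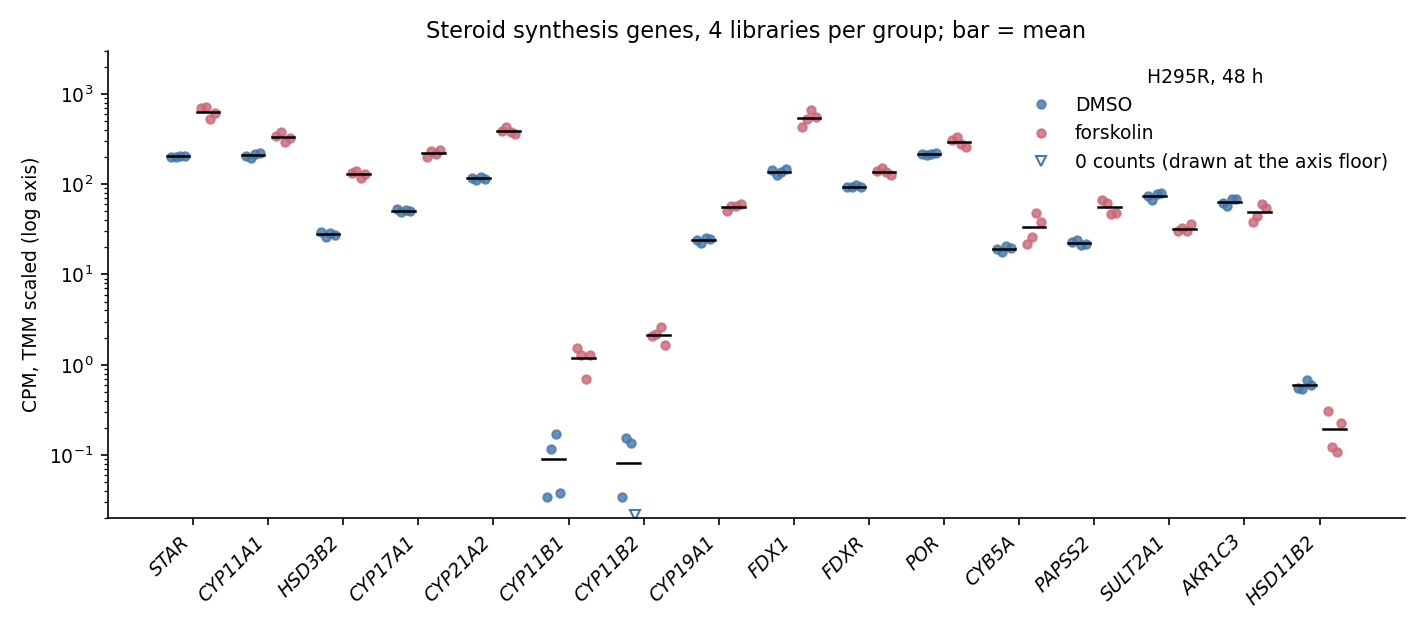
TMM-scaled CPM (log axis) of 16 steroid synthesis genes in the 4 DMSO and 4 forskolin libraries, with points for libraries and bars for group means; a triangle at the axis floor marks 0 counts. CYP17A1 went from a mean of 50.7 to 222 CPM and SULT2A1 from 74.7 to 32.3 CPM.

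TAC1, the precursor of substance P, had the highest log2 fold change among the genes named by the rule and rose by 5.22 (SE 0.39) on the log2 scale, from 0.417 ± 0.208 to 16.0 ± 6.20 CPM. GCNA, a germ cell nuclear protein, rose by 4.90 (SE 0.12), from 7.14 ± 0.706 to 214 ± 28.8 CPM. CGA, the common alpha subunit of the glycoprotein hormones, rose by 4.84 (SE 0.21) and UTS2, the precursor of urotensin II, by 4.47 (SE 0.29). FAM166B, SPRR1B, ADGRD1, TFPI2, IL7R and GDF10 followed, with log2 fold changes from 3.58 to 3.30, and TFPI2, a serine protease inhibitor, reached 484 ± 37.7 CPM in forskolin. Among genes that fell, HLF, a PAR bZIP transcription factor, went from 10.8 ± 1.18 to 1.08 ± 0.196 CPM (log2 fold change -3.31, SE 0.15). CUX2, PDE11A, SCN1A, DACT1, BMF, GBP2, UNC5B, PTPRZ1 and DOCK11 fell with log2 fold changes from -2.99 to -2.49. PDE11A encodes a phosphodiesterase that breaks down cyclic AMP and cyclic GMP. DACT1, a regulator of WNT signalling, fell from 159 ± 6.13 to 22.1 ± 2.73 CPM, and BMF encodes a pro-apoptotic BH3 protein.

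Of genes induced through CREB and of feedback genes of ERK signalling, more rose than fell. Of 19 tested CREB targets, 13 rose and 3 fell (14 and 3 adjusted over the list alone), with a median log2 fold change of 0.87 (camera, adjusted p = 2.3e-10; adjusted p = 0.033 with an estimated correlation). Besides CGA, FOS rose by 2.22 (SE 0.14), the orphan nuclear receptor NR4A1 by 1.42 (SE 0.08) and NPTX2, a neuronal pentraxin, by 1.24 (SE 0.08). Of 14 ERK feedback and early genes, 10 rose and 2 fell (11 and 2 adjusted over the list alone; camera, adjusted p = 3.4e-09; adjusted p = 0.096 with an estimated correlation). EGR1 rose 5.01-fold, from 13.4 ± 1.05 to 67.3 ± 5.14 CPM, the feedback inhibitor SPRY2 3.40-fold, the ETS factor ETV4 3.01-fold and the ERK phosphatase DUSP5 2.02-fold. Higher and lower CREB targets numbered 12 and 3 with library size alone and 7 and 4 on log2(TPM + 1) (medians 0.64 and 0.18), and ERK genes 8 and 2 with library size alone and 4 and 3 on log2(TPM + 1) (medians 0.59 and 0.18). For components of the cyclic AMP pathway the balance depended on the scaling. Of 26 tested, 6 rose and 8 fell (the same numbers adjusted over the list alone), and the list did not pass camera (adjusted p = 0.70; the median of -0.08 is below 0 while the mean of 0.05 and the test point up), and with the length trend removed 8 rose and 7 fell. The higher and lower components were 4 and 12 with library size alone and 2 and 18 on log2(TPM + 1). PRKAR2B, a regulatory subunit of protein kinase A, rose by 1.62 (SE 0.07) and the phosphodiesterases PDE3A and PDE7B by 1.70 and 1.01, while the anchoring protein AKAP12 fell by 1.21.

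Of beta-catenin targets and of genes of inhibin, activin and BMP signalling, more fell than rose. Of 18 beta-catenin target genes, 12 fell and 2 rose (12 and 3 adjusted over the list alone), with a median log2 fold change of -1.09 (camera, adjusted p = 4.3e-11; adjusted p = 0.022 with an estimated correlation). AXIN2 fell from 131 ± 2.02 to 49.4 ± 4.59 CPM, APCDD1 from 474 ± 12.0 to 172 ± 11.04 CPM, ISM1 from 54.6 ± 1.72 to 9.85 ± 1.198 CPM and LGR5 from 17.7 ± 0.992 to 5.94 ± 0.375 CPM. The members that rose were DKK1 and DKK4, secreted WNT inhibitors, DKK1 by 0.83 (SE 0.10) at a mean count of 226 (0.26 on log2(TPM + 1), limma adjusted p = 0.32) and DKK4 with a log2 fold change of 3.13 (SE 0.66) at a mean count of 10.9. Of 20 genes of inhibins, activins and BMPs, their antagonists and their responses, 11 fell and 1 rose (the same numbers adjusted over the list alone), with a median of -0.44 (camera, adjusted p = 8.8e-09; adjusted p = 0.022 with an estimated correlation). FST, which encodes the activin antagonist follistatin, fell by 2.43 (SE 0.07), and the BMP-responsive genes ID3, ID1 and SMAD7 had log2 fold changes of -2.43, -2.05 and -1.50. Lower and higher members were 13 and 2 with library size alone and 13 and 1 on log2(TPM + 1) in the WNT target list, and 13 and 1 with library size alone and 13 and 0 on log2(TPM + 1) in the inhibin list.

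Markers of the adrenal zones changed in both directions. Of 17 markers of the aldosterone-producing zona glomerulosa, 10 fell and 5 rose (the same numbers adjusted over the list alone), CYP11B2 among the latter, with a median of -0.50 (camera, adjusted p = 0.0029; adjusted p = 0.074 with an estimated correlation). LGR5, the neurofilament gene NEFM, CALN1 and the calcium channel gene CACNA1D had log2 fold changes of -1.57, -1.38, -1.38 and -0.998. Of 8 markers of the androgen-producing zona reticularis, 5 rose and 2 fell (6 and 2 adjusted over the list alone), with a median of 1.05 (camera, adjusted p = 0.0021; adjusted p = 0.096 with an estimated correlation). CYP17A1, PAPSS2 and TSPAN12 rose, the last by 1.32 (SE 0.14), and SULT2A1 fell. CYP17A1, PAPSS2, CYB5A, AKR1C3 and SULT2A1 also belong to the steroid synthesis list. Higher and lower markers were 3 and 10 with library size alone and 1 and 11 on log2(TPM + 1) for the glomerulosa, and 5 and 2 with library size alone and 3 and 2 on log2(TPM + 1) for the reticularis.

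**Figure D2:**
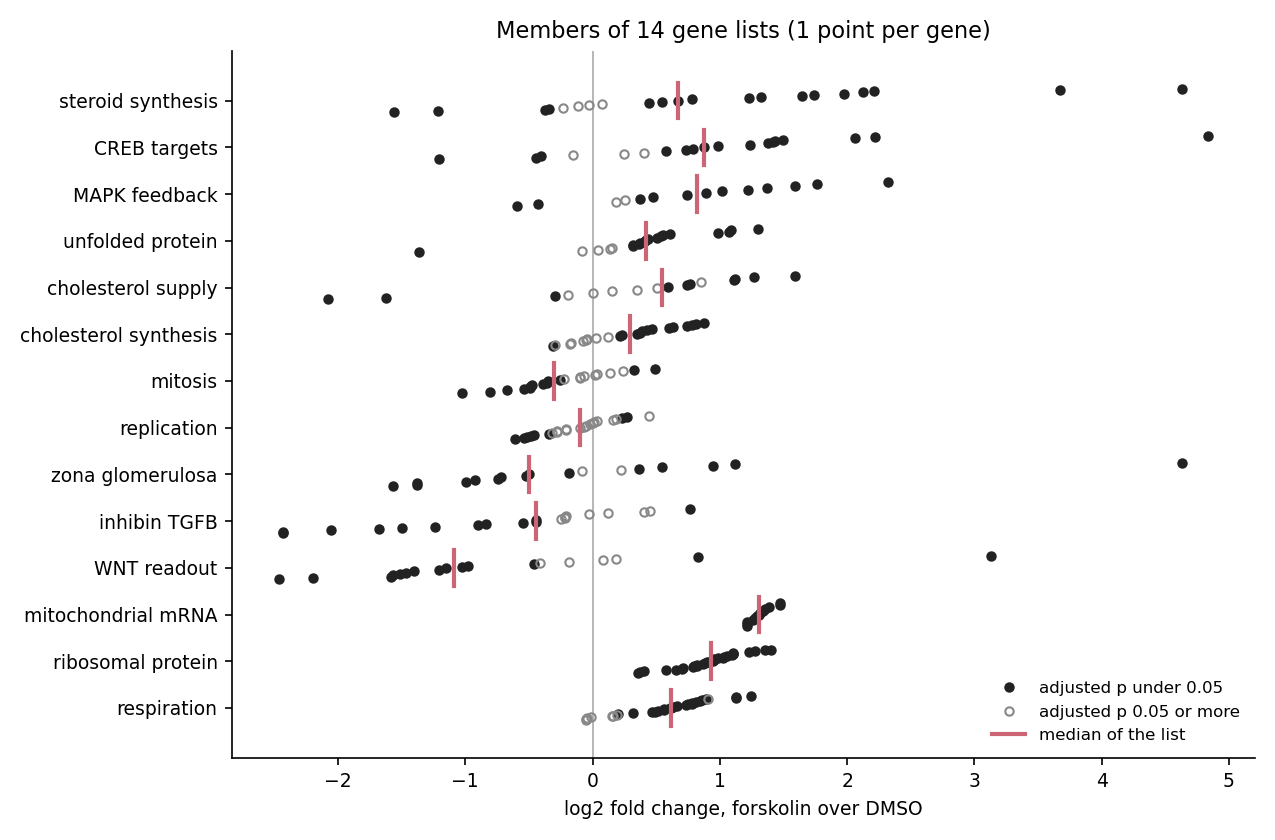
Log2 fold change (forskolin over DMSO) of the tested members of 14 gene lists, with 1 point per gene, filled where the adjusted p was under 0.05, and red bars for list medians. The WNT target list has a median of -1.09 and the CREB target list one of 0.87.

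MC2R, the ACTH receptor, rose 6.03-fold from 5.38 ± 0.514 to 32.4 ± 2.71 CPM, while its accessory protein MRAP had a log2 fold change of -2.47 (SE 0.47; edgeR adjusted p = 0.0018) at a mean count of 16.1. AGTR1, the angiotensin receptor, fell by 0.93, and NR3C2, the mineralocorticoid receptor, rose by 1.197. Of 17 receptor genes, 5 rose and 9 fell (5 and 10 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.69); higher and lower receptors were 4 and 10 with library size alone and 1 and 12 on log2(TPM + 1). Of 15 adrenal transcription regulators, 2 rose and 7 fell (the same numbers adjusted over the list alone; camera, adjusted p = 0.072, and 0.049 without forskolin replicate 1), with 0 and 9 with library size alone and 0 and 10 on log2(TPM + 1). ZNRF3, a WNT receptor ubiquitin ligase, fell by 1.03 and NR2F2, an orphan nuclear receptor, fell by 0.71. NR5A1, the steroidogenic factor, had a log2 fold change of 0.16 (SE 0.10; edgeR adjusted p = 0.22). It passed at 0.25 without forskolin replicate 3 (edgeR adjusted p = 0.020), and was -0.06 with library size alone and -0.52 on log2(TPM + 1).

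Of genes of cholesterol handling and of the unfolded protein response, more rose than fell. Of 16 genes of cholesterol uptake, storage and release, 7 rose and 3 fell (8 and 3 adjusted over the list alone), with a median of 0.55 (camera, adjusted p = 0.016; adjusted p = 0.096 with an estimated correlation, and 0.067 with library size alone). The lipoprotein receptor SCARB1 rose from 915 ± 7.30 to 2206 ± 143 CPM, the esterifying enzyme SOAT1 from 782 ± 35.8 to 1686 ± 131 CPM and the exporter ABCA1 3.01-fold, while the lipoprotein receptor VLDLR fell by 1.62. Of 22 cholesterol synthesis genes, 13 rose and 1 fell (13 and 2 adjusted over the list alone; camera, adjusted p = 0.016; adjusted p = 0.45 with an estimated correlation, and 0.064 with library size alone). SC5D, a sterol desaturase, rose by 0.78 and ACAT2, an acetyl-CoA acetyltransferase, by 0.81. Of 20 genes of the unfolded protein response, 15 rose and 1 fell (the same numbers adjusted over the list alone; camera, adjusted p = 1.6e-04; adjusted p = 0.19 with an estimated correlation). XBP1, a transcription factor of that response, rose 2.46-fold, SDF2L1 2.12-fold and the disulphide isomerase PDIA6 1.53-fold. With library size alone, 6 rose and 4 fell in the uptake list, 6 and 5 in the synthesis list and 5 and 1 in the unfolded protein list. Higher and lower genes on log2(TPM + 1) were 2 and 5, 0 and 8 and 1 and 3. On that scale the medians of these lists were -0.04, -0.42 and -0.29, and PDIA6 had -0.08.

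More mitosis genes fell than rose. Of 22 mitosis genes, 12 fell and 2 rose (the same numbers adjusted over the list alone), with a median of -0.30 (camera, adjusted p = 0.039; adjusted p = 0.32 with an estimated correlation). The call of the list ended without DMSO replicate 4 (camera adjusted p = 0.052), without forskolin replicate 4 (0.051) and with library size alone (0.059). Lower and higher mitosis genes were 15 and 0 with library size alone and 20 and 0 on log2(TPM + 1). KIF20A, a mitotic kinesin, fell from 114 ± 3.68 to 55.8 ± 10.7 CPM, the topoisomerase TOP2A fell by 0.81 and NUSAP1, a spindle protein, fell by 0.48 on the log2 scale. Of 23 replication genes, 6 fell, MCM5 (-0.52) and UHRF1 (-0.48) among them, and 2 rose (6 and 1 adjusted over the list alone; camera, adjusted p = 0.36), and the numbers were 11 and 0 with library size alone and 19 and 0 on log2(TPM + 1).

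Endothelial and leukocyte markers were sparse. None of 9 endothelial markers passed the expression filter, and of 9 leukocyte markers 3 did and none passed the test, with no difference over the list alone either. The leukocyte marker LYZ stood at 4.72 CPM in DMSO replicate 2 against 0.549 to 0.758 in the other DMSO libraries. In forskolin replicate 4 it stood at 12.2 CPM against 0.702 to 1.39 in the other forskolin libraries. LYZ is not counted among the named genes of the closing sections. Of 9 tested fibroblast markers, 5 fell and 2 rose (the same numbers adjusted over the list alone; camera, adjusted p = 0.035; adjusted p = 0.15 with an estimated correlation). That call also ended without DMSO replicate 4 (camera adjusted p = 0.052) and with library size alone (0.11). ACTA2, smooth muscle actin, fell by 0.88 and FAP, a surface protease, fell by 0.71. LUM and DCN, matrix proteoglycans at mean counts of 12.6 and 13, had log2 fold changes of 2.30 (SE 0.48) and 1.46 (SE 0.46). The call of DCN ended in 5 of the 8 fits that left out 1 library, with edgeR adjusted p of 0.051 (without DMSO replicate 1), 0.068 (DMSO 2), 0.063 (DMSO 3), 0.051 (forskolin 3) and 0.088 (forskolin 4). Of 10 markers of ovarian granulosa cells, 4 fell and 2 rose (the same numbers adjusted over the list alone; camera, adjusted p = 0.015; adjusted p = 0.096 with an estimated correlation, and 0.061 with library size alone). Without forskolin replicates 3 and 4, 3 fell and 3 rose. Lower and higher markers were 6 and 2 with library size alone and 6 and 1 on log2(TPM + 1), and of the fibroblast list 5 and 2 with library size alone and 7 and 2 on log2(TPM + 1). FST fell, KITLG, which encodes the KIT ligand, fell by 1.39, and CYP19A1 rose.

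Mitochondrially encoded mRNAs and ribosomal protein mRNAs rose in forskolin by amounts that differed between libraries. The 13 mitochondrial mRNAs made up 7.71% ± 0.172 of the counts in DMSO and 15.2% ± 6.01 in forskolin (SD, n = 4; exact permutation, two-sided, p = 0.0286, the smallest the design allows, adjusted p = 0.0476 over 5 measures). Forskolin replicates 1 to 4 had 9.53, 11.6, 22.97 and 16.9%, and without forskolin replicate 3 the mitochondrial mRNA share difference of 7.54 percentage points became 4.96. All 13 rose in the edgeR test, also adjusted over the list alone, MT-ND4 by 1.39 (SE 0.31) and MT-CO3 by 1.29 (SE 0.30), with a median of 1.31 (camera, adjusted p = 0.0024; adjusted p = 0.60 with an estimated correlation, and 0.052 with fry). All 30 ribosomal protein genes rose, also adjusted over the list alone, with a median of 0.93 (camera, adjusted p = 1.9e-07; adjusted p = 0.50 with an estimated correlation), RPL6 by 0.71 and RPL7 by 0.79. Of 30 nuclear genes of the respiratory chain, 22 rose and 0 fell (24 and 0 adjusted over the list alone), with a median of 0.61 (camera, adjusted p = 9.2e-04; adjusted p = 0.46 with an estimated correlation), NDUFA9 by 0.66 and UQCRFS1 by 0.62. On log2(TPM + 1) 13 mitochondrial, 11 ribosomal protein and 1 respiratory chain genes rose, 3 of the last fell, and the 3 medians were 0.46, 0.19 and -0.09, NDUFA9 had -0.07 and UQCRFS1 -0.07. The ribosomal list's share went from 1.22% ± 0.0835 to 1.84% ± 0.318, and that of the 10 highest genes from 7.96% ± 0.225 to 15.2% ± 5.76 (exact permutation, two-sided, adjusted p = 0.0476 for each). The share of the 10 highest genes was 9.76, 11.7, 22.7 and 16.7% in forskolin replicates 1 to 4, close to the mitochondrial share in each. It is therefore not a separate line of evidence. No difference was detected in library totals (exact permutation, two-sided, p = 0.83) or in genes with at least 10 counts (p = 0.34).

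Libraries also differed in how counts depended on transcript length. In the 10% of genes with the shortest transcripts, the median deviation from the DMSO mean was 0.12, 0.35, 0.83 and 0.50 on the log2 scale in forskolin replicates 1 to 4, and in the 10% with the longest -0.11, -0.27, -0.32 and -0.21. DMSO replicates 1 to 4 lay at -0.057, -0.095, 0.085 and 0.085 for the shortest and 0.048, 0.106, -0.074 and -0.075 for the longest. In both groups, the shortest lay lower in replicates 1 and 2 than in 3 and 4. Without forskolin replicates 3 and 4, a choice made after seeing these values, 3029 genes were higher and 2869 lower. The medians were then 0.57 for mitochondrial, 0.52 for ribosomal protein and 0.34 for respiratory chain genes, 0.63 for steroid synthesis and -0.98 for WNT target genes. With each library's trend on transcript length removed, the medians were 0.79 for mitochondrial, 0.39 for ribosomal protein and 0.26 for respiratory chain genes, of which 17 rose, and with library size alone 0.995, 0.64 and 0.35.

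**Figure D3:**
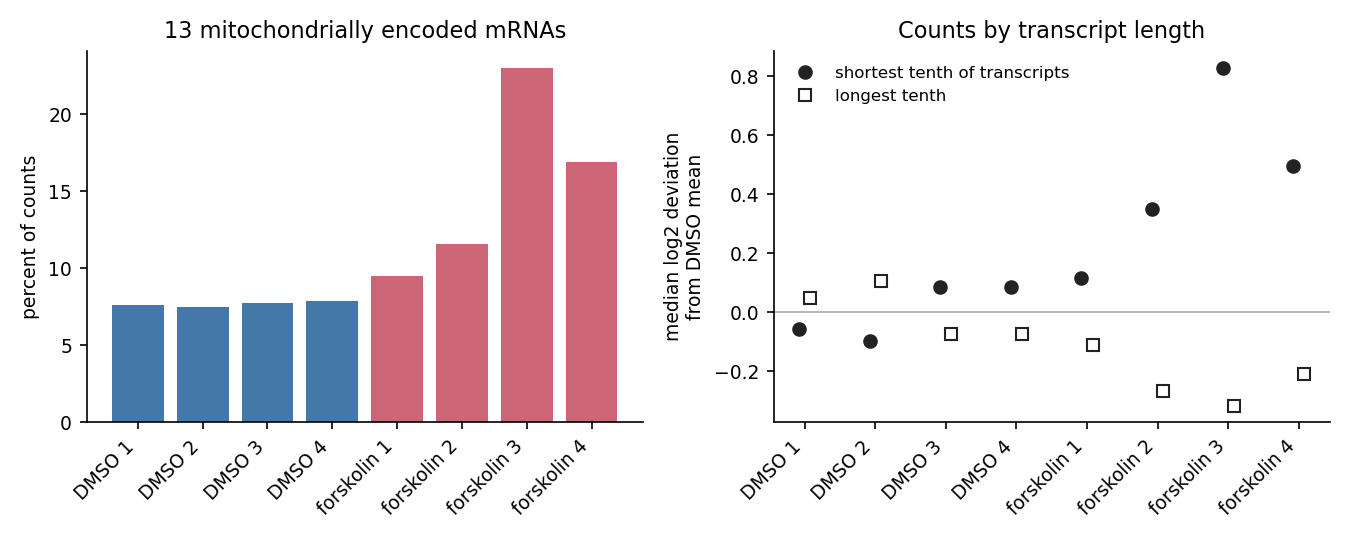
Percent of counts from the 13 mitochondrially encoded mRNAs in each library (left, bars), and median log2 deviation from the DMSO mean in the 10% of genes with the shortest and the longest transcripts (right). Forskolin replicate 3 had the highest mitochondrial share, 22.97%, and the largest deviation of short transcripts, 0.83.

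DENND1A, on chromosome 9 at 123379658 to 123930126 (ENSG00000119522.14), is a regulator of RAB35 in endocytosis and lies at a locus tied to polycystic ovary syndrome. Its level did not pass the test, at 36.1 ± 0.280 CPM in DMSO and 33.4 ± 2.72 CPM in forskolin (SD, n = 4). The log2 fold change was -0.11 (SE 0.07, 95% interval -0.29 to 0.07; edgeR adjusted p = 0.25), 0.07 with the effective length offset, -0.34 with library size alone (edgeR adjusted p = 0.0504) and -0.54 on log2(TPM + 1) (limma adjusted p = 0.056). With each library's trend on transcript length removed, it was -0.0083 (edgeR adjusted p = 0.92). Of 23 tested genes named for such loci, 3 rose and 6 fell (2 and 4 adjusted over the list alone; camera, adjusted p = 0.50), and the numbers were 1 and 10 with library size alone and 0 and 16 on log2(TPM + 1). AOPEP, an aminopeptidase gene, fell by 1.03 and the potassium channel gene KCNA4 fell by 0.56. INSR, the insulin receptor, rose by 0.58 and THADA by 0.44, with -0.09 and -0.20 on log2(TPM + 1), and the call of THADA ended with library size alone (0.21, edgeR adjusted p = 0.25).

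The mean length of DENND1A transcripts, weighted by RSEM's abundance estimates over 13 annotated transcripts, was 3559 ± 78.7 bases in DMSO and 3128 ± 59.8 bases in forskolin (SD, n = 4), shorter in each forskolin library than in every DMSO library. The log2 shift was -0.19 (SE 0.02). DENND1A was to be reported whatever its value, and its unadjusted limma p was 5.6e-05. An exact two-sided permutation gave p = 0.0286, the smallest the design allows. By limma p, DENND1A ranked 2 of 10421 genes. It did not pass the adjustment over all genes (limma adjusted p = 0.18, and between 0.13 and 0.33 over the alternatives). Its rank was 4, 8, 12 and 5 without DMSO replicates 1 to 4, 7, 12, 10 and 6 without forskolin replicates 1 to 4, and 46 without forskolin replicates 3 and 4 together. No gene passed: limma called 0 of 10421 genes, against 997 at an unadjusted p under 0.05, of which 753 had shorter and 244 longer transcripts in forskolin. The effective length column gave 2 genes (GAS5 and GSTO2), and leaving out forskolin replicate 3 gave 1 (ABHD14A). GSTO2, a glutathione transferase gene that ranked first, had 1724 ± 78.3 bases in DMSO and 1261 ± 37.0 in forskolin (limma adjusted p = 0.063).

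**Figure D4:**
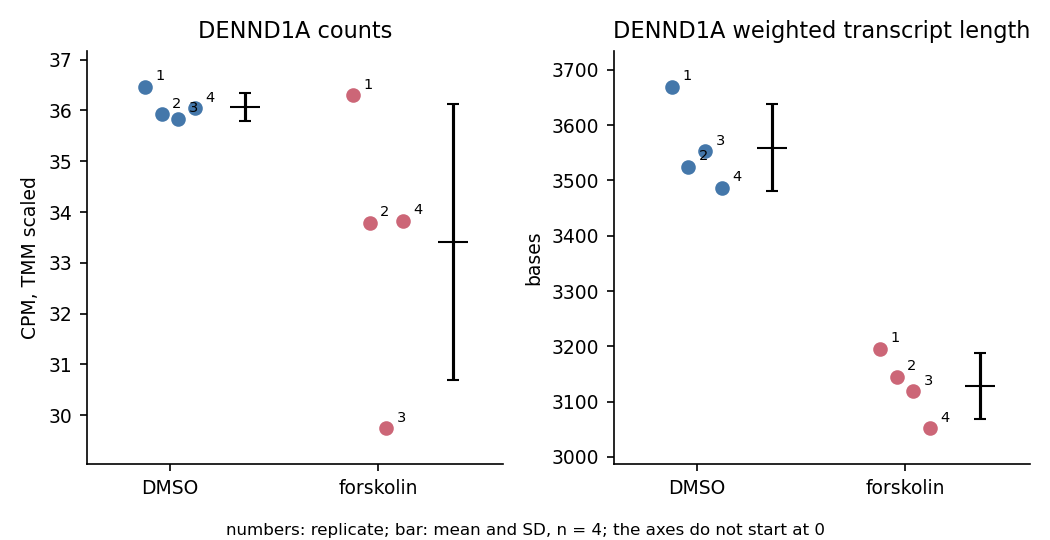
DENND1A in the 4 DMSO and 4 forskolin libraries, as TMM-scaled CPM (left) and as RSEM's weighted transcript length in bases (right), with points for libraries (numbers are replicates) and bars for mean and SD; axes do not start at 0. Counts overlap between the groups (36.1 and 33.4 CPM on average) and lengths do not (3559 and 3128 bases).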

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

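For each named gene and library measure, the values of the 4 libraries of a group were checked for 1 library far from the other 3, by Dixon's ratio of the gap to the range. Of 260 groups checked, 9 had such a library, where chance gives about 1 in 20, or 13. LYZ, which had 1 library far above the others in each group, was not among those checked. In DMSO, HSD17B1 stood at 5.92 CPM in replicate 2 against 5.15 to 5.20 in the others, and IL7R at 12.3 CPM in replicate 2 against 12.9 to 12.96. MC2R stood at 4.61 CPM in DMSO replicate 1 against 5.56 to 5.73, and MCM5 at 84.9 CPM in DMSO replicate 4 against 91.9 to 93.2. In forskolin, SPRY2 stood at 37.9 CPM in replicate 1 against 42.1 to 43.0. In forskolin replicate 2, GDF10 stood at 28.7 CPM against 22.7 to 23.5, and XBP1 at 129 CPM against 108 to 109. In forskolin replicate 3, BMF stood at 1.39 CPM against 2.03 to 2.07, and HMOX1 at 3.22 CPM against 6.04 to 6.54.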

How the results depend on the processing

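Leaving out forskolin replicates 3 and 4 together, removing the length trend, and the variance trend on mean count were chosen after seeing the data. Of 123 named genes 116 passed the test, and 69 of these kept direction and call under each setting run. With library size only, log2(TPM + 1) and glmTreat set aside, 111 did, the exceptions being AKR1C3, CLTB, CYB5A, DCN and STS. Library size only gave 1674 higher and 5300 lower genes (405 and 961 at least 2-fold). Against a fold of 1.5, glmTreat gave 1052 genes, 484 higher and 568 lower (413 at least 2-fold higher), since it asks for a larger change. On log2(TPM + 1), 403 were higher and 8450 lower (83 and 1469 at least 2-fold). That scale turned the log2 fold changes of POR (-0.27), CYP11A1 (-0.035), FDXR (-0.054), INSR (-0.089), THADA (-0.20), CLTB (-0.18), PDIA6 (-0.079), NDUFA9 (-0.073), UQCRFS1 (-0.072) and SRXN1 (-0.24), and among genes that had not passed, NR5A1 (-0.52), MALAT1 (-0.44) and HSD17B3 (-0.25). Of the last 3, MALAT1 passed as lower there (limma adjusted p = 0.045). On that scale the median of all genes moved by -0.49, and the cause of the changes in these counts and values was not tested. Other turns were in genes that did not pass the test, and the cause was not tested. With library size only, NR5A1 was -0.060 and HSD17B3 -0.18. With the effective length offset, DENND1A was 0.068 and HSD17B1 0.057. With the length trend removed, HSD17B1 was 0.15 and HSD17B3 -0.32. Without forskolin replicates 3 and 4, HSD17B3 was -0.54 and HSD17B4 0.0033. Leaving out 1 library at a time, HSD17B1 lay between -0.082 and 0.055 and HSD17B3 between -0.19 and 0.31. The same fits gave 5316 to 7709 genes changed, 14 to 18 lists called, a steroid synthesis median of 0.56 to 0.70, and 0 to 1 genes with a transcript length shift, the highest without forskolin replicate 3. Of 30 lists, 16 were called with the preset correlation, 4 with an estimated correlation (steroid synthesis, CREB targets, inhibin and BMP, WNT targets) and 19 with fry. The effective length column gave 2 length shifts. Replicate numbers did not pair the samples 1 to 1: same-numbered libraries had correlations of deviations of 0.0859, 0.0107, 0.0686 and 0.0241, not all above 0.1. DMSO replicate 4 correlated best with forskolin replicate 3 (0.172). The groups did share a division of replicates 1 and 2 from 3 and 4. Correlations between DMSO and forskolin libraries were positive within it (0.0041 to 0.172) and negative across it (-0.152 to -0.0038). The deviation of genes with the shortest transcripts followed the same division in both groups. No term for this division alone was fitted, and its source was not tested. The replicate block gave 3628 higher and 3526 lower genes, ended the call of the fibroblast list (camera adjusted p = 0.051) and ended the call of no named gene. Depth limits CYP11B1, CYP11B2, HSD11B2, HSD17B3, MRAP, DKK4, LUM and DCN, at mean counts of 10.6 to 26.1.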

Other observations

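Genes of chromaffin cells, the catecholamine-producing cells of the adrenal medulla, went both ways: of 6 tested markers, 2 rose and 3 fell (the same numbers adjusted over the list alone; camera, adjusted p = 0.88). Without forskolin replicates 3 and 4, 2 rose and 2 fell, and on log2(TPM + 1) 1 rose and 4 fell. SCG2, a secretogranin, rose by 2.25 (SE 0.20) on the log2 scale and CHGB, a chromogranin, fell by 1.66 (SE 0.12). Of 24 matrix and adhesion genes, 9 rose and 10 fell (9 and 12 adjusted over the list alone; camera, adjusted p = 0.57), and the numbers were 4 and 12 with library size alone and 1 and 13 on log2(TPM + 1). The integrin ITGA1 rose from 691 ± 22.1 to 1549 ± 73.6 CPM and the protease inhibitor TIMP1 by 0.77, while vimentin (VIM) fell from 867 ± 37.8 to 386 ± 64.6 CPM and ITGAV fell by 0.68. Among 15 insulin-like growth factor genes, 5 rose and 4 fell (the same numbers adjusted over the list alone; camera, adjusted p = 0.83, where the median of -0.11 and the mean of -0.02 are below 0 and the test points up). With library size alone 4 rose and 7 fell, and on log2(TPM + 1) 0 and 9. IRS1, an adaptor of the insulin receptor, rose by 1.005 and IGFBP5 fell by 1.96.

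The ATF4, glycolysis, antioxidant, glucocorticoid and clathrin lists did not pass camera. Of 20 ATF4 and amino acid genes, 8 rose and 2 fell (the same numbers adjusted over the list alone; camera, adjusted p = 0.061, and 0.040 and 0.033 without forskolin replicate 3 or 4, and 0.0034 without both). TRIB3 rose 2.61-fold and the serine synthesis enzyme PSAT1 1.64-fold. Of 23 glycolysis and hypoxia genes, 9 rose and 4 fell (10 and 4 adjusted over the list alone; camera, adjusted p = 0.061). That list passed without DMSO replicate 1 (0.042), 2 (0.047) or 3 (0.0499) and without forskolin replicate 3 (0.038) or 4 (0.029) or both (0.0044), each a camera adjusted p. PFKP, a phosphofructokinase, rose by 0.84 and the pyruvate dehydrogenase kinase PDK1 by 1.17. Of 19 antioxidant genes, 8 rose and 3 fell (10 and 4 adjusted over the list alone; camera, adjusted p = 0.42), with GPX1 at 1.05, SRXN1 at 0.44 (-0.24 on log2(TPM + 1)) and HMOX1 at -0.98. The call of SRXN1 ended with library size alone (0.20, edgeR adjusted p = 0.19). With library size alone 2 and 6 antioxidant genes were higher and lower, and with the length trend removed 4 and 5, with a median of -0.04. On log2(TPM + 1) the higher and lower genes were 1 and 11 in the antioxidant, 1 and 8 in the ATF4 and 0 and 11 in the glycolysis list. The numbers in the ATF4 and glycolysis lists with library size alone were 5 and 3 and 6 and 5, and the medians of the ATF4, glycolysis and antioxidant lists were -0.04, -0.04 and -0.03. Of 12 glucocorticoid-responsive genes, 3 rose and 4 fell (the same numbers adjusted over the list alone; camera, adjusted p = 0.88), DUSP1 by 0.79 and KLF9 with -0.93. In that list, 3 rose and 3 fell without forskolin replicate 3, and 4 rose and 3 fell without both replicate 3 and replicate 4, while the numbers were 2 and 4 with library size alone and 0 and 7 on log2(TPM + 1). Of 21 genes of DENND1 proteins, RAB35 and the clathrin coat, 2 rose and 7 fell (3 and 8 adjusted over the list alone; camera, adjusted p = 0.42). Without forskolin replicates 3 and 4, 4 rose and 3 fell, and the numbers were 0 and 12 with library size alone and 0 and 15 on log2(TPM + 1). The adaptor AP2B1 fell by 0.68, and the clathrin light chain CLTB rose by 0.49, with 0.25 (edgeR adjusted p = 0.14) once the length trend was removed and -0.18 on log2(TPM + 1), and its call ended with library size alone (0.26, edgeR adjusted p = 0.15).

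The tests of random lists, of nuclear RNAs and of DENND1A lengths below were chosen after the results were seen, and the counts over other splits before. Over the 35 splits of the 8 libraries into 4 and 4, 1 split, the real one, gave as many genes changed (6990, against at most 0 in another), and 1 gave as many lists called (16, against at most 14). The real split gave the highest count of both, for the lists by a small margin, but 1 of 35 is the lowest share that the splits allow. Every other split puts libraries of both treatments on a side. The treatment difference then adds to the spread within sides, so few calls there do not exclude chance. The 14 lists came from DMSO replicate 1 with forskolin replicates 1 to 3 against the rest, a split that keeps 3 libraries of each group together. The 18 splits with 2 libraries of each group on each side gave at most 7, and 4 lists were called with an estimated correlation. For transcript length after adjustment, the real split gave 0 genes (at most 1 in another), so all 35 splits gave as many and the count decides nothing. At an unadjusted p under 0.05, 1 split gave as many as the real 997 (at most 688 in another). The same limits hold for that number, which names no gene.

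The rise of mitochondrially encoded, ribosomal protein and respiratory chain mRNAs goes with a trend on transcript length between libraries, largest in forskolin replicate 3. The mitochondrial median of 1.31 lay at percentile 100 of 10000 random lists of nuclear genes of the same lengths. The median of 0.79 over the 60 ribosomal protein and respiratory chain genes lay at percentile 100 of its own. It was 100 for the ribosomal protein list and 99.9 for the respiratory chain list alone. Members of these lists moved together, with estimated correlations of 0.997 (mitochondrial), 0.93 (ribosomal protein) and 0.33 (respiratory chain). Genes drawn at random need not, so their medians spread less and the percentiles alone do not decide against the trend. With the trend removed the mitochondrial median was 0.79 (12 of 13 called), the ribosomal protein median 0.39 (27 of 30, against 0.93 and 30 before) and the respiratory chain median 0.26 (17 of 30, against 0.61 and 22), so part of the rise of each went with the trend. Loss of cytoplasmic RNA would also raise RNAs held in the nucleus by about as much, and their median over 9 RNAs was 0.072 (SD 0.37). The bound that sets this against 0.79 was chosen after the value was seen, and an earlier bound had decided nothing. MALAT1 rose by 0.70 with the trend removed. With the trend kept, MALAT1 stood at 283, 219, 490 and 429 CPM in forskolin replicates 1 to 4 against 231 to 268 in DMSO. MEG3, NEAT1, JPX, PVT1 and KCNQ1OT1 also lay above every DMSO library in forskolin replicates 3 and 4. TUG1, FTX and FIRRE did not. The median, which averages over the forskolin libraries, does not decide against such a loss. That loss, RNA quality and an effect of forskolin, which may vary in size between the libraries, stay open. The fragment length implied by RSEM's effective lengths was 282 bases in forskolin replicate 3 and 295.5 to 304 in the others. Mitochondrial rRNA was 0.529, 0.591, 1.29 and 0.980% of counts in forskolin replicates 1 to 4 against 0.432 to 0.494% in DMSO.

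The shorter DENND1A transcripts are a hypothesis, since the gene did not pass the adjustment over all genes. The length trend between libraries was argued against as the whole cause: with each library's deviation for genes of similar length as a term, forskolin minus DMSO was -342 bases (95% interval -565 to -119), though the trend term itself was poorly fixed (interval -693 to 1937 bases per log2 unit) with 5 degrees of freedom. Forskolin replicates 1 to 4 had differences from the DMSO mean of -363, -413, -439.6 and -507 bases, so replicate 1 had 82.6% of the fall in replicate 3, where the trend gives 21.0% for the 10% of genes with DENND1A's length, 14.2% for the shortest and 34.8% for the longest. A general shortening of transcript mixes stays open. DENND1A lay at percentile 4.32 of the shifts of 3147 genes of similar length, within the bounds set for this explanation, and 136 of them shortened more. Only a shortening by the same amount in each gene is too small, with a median log2 shift of -0.0085 against -0.19 for DENND1A. A change of isoform mix by forskolin, which may account for the shift, also stays open.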
